A study of Aplysia californica with 2 samples.

How the data were processed

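RNA recovered with a custom antibody against kinesin, the motor protein that carries cargo along microtubules, was compared with a control in neurons from the central nervous system of the sea hare Aplysia californica. Each of 2 Agilent array designs, called AAA and DAA in the labels, was hybridised once. Per the labels, the kinesin immunoprecipitate (IP) carried Cy3 and the control carried Cy5 on both arrays, and the RNA was amplified in a single round before labelling. Both an anti-kinesin and a non-specific secondary antibody are listed under the IP channel, so that the control was made with the second one is inferred. Because dye and sample were never exchanged, a dye effect cannot be separated from an IP effect. The labels do not say whether the arrays received separate extracts.

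Per the file headers and column names, the deposited scanner files hold spot intensities from Agilent Feature Extraction on a linear scale, as mean, local background, background-subtracted and processed signals. They also hold a log10 ratio of Cy5 over Cy3 per spot. The submitters' processing notes name Agilent Feature Extraction version 7.0, while the header of the AAA file gives 8.5.1.1. The AAA header records spatial detrending, a linear and lowess dye normalization, and surrogate values in place of signals near background. The DAA file carries no parameter block, and its deposited intensities are rounded to 3 significant digits. The authors' series matrix column equals minus the deposited log10 ratio to within 0.005 on both arrays. It is therefore log10 of IP over control, not centred further, and its median was 0 on both arrays.

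The main value was log2 of the processed IP signal over the processed control signal. Control spots and spots with an outlier flag were left out (24 spots on AAA and 9 on DAA), and the spots of a probe were averaged. A probe was tested where at least 50% of its spots were well above background in at least 1 channel. Ratios were centred on the median of the tested probes, which took off 0.04 on AAA and 0.43 on DAA. No further loess was applied, since an IP can move many RNAs the same way. The AAA processed signals already carry the scanner software's linear and lowess dye normalization, so the main AAA ratios are not free of a lowess correction. For DAA the dye normalization is not recorded. The size threshold was 2-fold. With 1 array per design, no p-value was computed across genes within an array.

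Where only 1 channel of a probe was well above background, a fold is given as a bound ("at least"). The bright channel was set against the higher of the dim channel's own signal and the lowest signal among probes well above background in that channel, after centring. These bounds are open to dye bias and depend on the background the scanner software took off.

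Gene names came from the target names in the files. Of 134 targets other than clones and contigs, 126 carry a GenBank accession. None of these accessions was in the AplCal3.0 RefSeq table used here, and 5 of the 46 gene names read from the targets were a symbol or synonym there. All other targets kept the identifiers in the files. The 25 gene lists were text patterns fixed before the data were examined. A rule for naming genes was fixed at the same time. It takes the 10 highest and 10 lowest annotated genes whose brightest probe was well above background in both channels and unsaturated, with all spots and probes on the same side of 0. It adds the highest, lowest and brightest member of each list and a set of standard neuronal and cytoskeletal genes where annotated. Some genes outside this rule are described too, among them Panx-2, Panx-3, Panx-4, soluble guanylate cyclase, PKG, PKA (N4) and Serine dehydratase. A gene is named by its brightest probe. The 7 functional groups of named genes were made by hand after the values were seen. A list or group with at least 5 measured members was set beside 10000 random sets of the same size, matched on mean signal, which applied to 1 group. List medians are means over probes per gene and the median over genes. Targets beyond the named genes are limited to 2 per direction and array.

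The 795 probes present on both arrays were compared through same-sign shares, correlation across probes, and limma (lmFit and eBayes) of the log ratio against 0 over the 2 arrays, with Benjamini-Hochberg adjustment at 0.05. Alternatives planned before the data were examined were normexp (offset 50) with loess, normexp with median centring, no centring, no detection filter, detection in both channels, the series matrix values, each spot on its own, other fold thresholds, and saturated spots left out. A background set at each channel's median non-control spot and removal of a trend with probe GC content were added after the data were seen. The software was R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

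The 2-fold counts, the list percentiles, the limma fit and the normalization and background settings were tested on simulated data. With the spot spread of the AAA array over 15921 probes, 100% of 50 probes set 3-fold higher passed 2-fold, as did 12% of 50 set 1.5-fold higher and 0.0064% of the unchanged. With the spot spread of the DAA array over 5412 probes, 78% of 50 probes set 3-fold higher passed, and so did 10.5% of the unchanged. For the shared features, limma recovered 100% of 40 probes set 4-fold higher among 167 over 20 draws when the arrays differed by an SD of 0.30, and 7.63% at the SD of 1.52 seen between these arrays. The background set at the median non-control spot returned a simulated log2 ratio of 2 as 1.92 where most spots were empty, and as 3.96 where most spots carried signal. The number of arrays limits the precision of every value.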

Results

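The series asks which RNAs are held by the kinesin complex, and so are carried from the cell body toward synapses, in neurons of the sea hare Aplysia californica. RNA from a kinesin pull-down (IP) was compared with control RNA on 2 array designs, with 1 array of each and no replicate of either. On the AAA array, 70.1% of the non-control spots were well above background in the IP channel and 62.2% in the control channel. On the DAA array these shares were 10.3% and 7.40%. All ratios are IP over control, centred on the median of the array. The SD between spots of a probe, on the log2 scale, was 0.29 on AAA and 0.62 on DAA, and it covers technical error alone. It rests on 10985 probes on AAA but on 54 on DAA, where 41230 of 41495 probes had a single spot. Over the 14 such DAA probes measured in both channels it was 0.77. No target name on either array contained the word kinesin, so the bait's own RNA could not be followed by name, and no unnamed clone or contig, the highest included, was excluded as its source.

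Some named genes had every tested probe and spot on 1 side of 0 on the AAA array. Those above 0 included the neuropeptide precursor, FMRFamide, NOS, NOS 2, Panx-1, HCN and the GABA A receptor alpha. Those below 0 included the potassium channel, AMPA, P2X4-2, Vanilloid and the non-alpha nicotinic acetylcholine receptor. The neuropeptide precursor, the source of a secreted peptide, had a log2 ratio of 0.94 on its brightest probe and of 1.82 (SD 0.04, 3 spots) and 1.99 on the others. FMRFamide, the precursor of a family of cardioactive and modulatory peptides, lay above 0 on all 3 probes, with 0.29 on the brightest, which became -0.01 after normexp with median centring. NOS, the enzyme that makes nitric oxide, was 2.06-fold higher in the IP on its brightest probe, and its mean over 3 probes was 1.01 (SD 0.16). NOS 2, a second nitric oxide synthase entry, was 1.45-fold higher, with all 3 probes above 0. Soluble guanylate cyclase, the receptor for nitric oxide, was above 0 on 3 of its probes, with a mean of 0.76 over all tested probes, but its brightest probe read -0.38. PKG, the kinase that cyclic GMP activates, read -0.06 on its brightest probe and 0.01 with the median non-control spot as background. Its mean was 0.09 (SD 0.82), with 1 of 3 probes above 0 and another at -0.65. Of the 13 tested probes of NOS, NOS 2, soluble guanylate cyclase and PKG, 5 had a control not well above background. The means of these 4 nitric oxide and cyclic GMP genes were all above 0, with a median of 0.62, but after normexp and loess 3 of the 4 were above 0 and the median was 0.10. With the median non-control spot as background 2 of the 4 were above 0 and the median was 0.05.

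Pannexins are membrane channel proteins, and the mean over probes was above 0 for all 4 on the AAA array, with a median of 0.53. Panx-1 was 2.49-fold higher in the IP on its brightest probe and lay above 0 on all 3. Panx-3 was 2.10-fold higher on its brightest probe, with 6 of 6 probes above 0, though not all spots of these probes were. Of the 14 tested probes of the 4 pannexins, 7 had a control not well above background. Panx-4 was at least 2.29-fold higher on its brightest probe, with the control not well above background, while another of its probes read -0.37. Panx-2 read 0.13, and -0.01 with the median non-control spot as background. After normexp and loess all 4 means stayed above 0 with a median of 0.11. With the median non-control spot as background 3 of the 4 were above 0 and the median was 0.09.

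The receptor and channel group held 8 measured genes, of which 5 lay below 0 and none reached 2-fold on its mean. Its median log2 ratio was -0.43, inside the 95% range of random sets of the same size matched on signal (-0.44 to 0.43), and it was -0.11 after normexp and loess and -0.01 with the median non-control spot as background. The groups were made after the values were seen, so their medians are descriptive. The potassium channel read -0.63 on its brightest probe, with all 3 probes below 0. The non-alpha nicotinic acetylcholine receptor, which opens on binding acetylcholine, read -0.26. AMPA, named for a class of glutamate receptor, read -0.53 (SD 0.45, 3 spots). P2X4-2, named for a channel opened by ATP, read -0.49, and Vanilloid read -0.41 on its single tested probe. The files give Vanilloid and FMRFamide the same accession, so the name of the first is uncertain. HCN, a channel opened by hyperpolarisation, went the other way at 0.52, with all 3 probes above 0. The GABA A receptor alpha read 0.55 on its single tested probe, and NMDAR1-1 read 0.61 on one probe and -0.21 on the other.

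Cytoskeletal RNAs showed no common direction on the AAA array. Actin read 0.09 on its brightest probe, though another of its probes read 1.09 (SD 0.17, 3 spots). Beta-tubulin read -0.13 and -0.68 (SD 0.33, 3 spots) on its 2 tested probes, the first of which was 0.00 after normexp with median centring. Rac, a small GTPase that remodels actin, was 1.70-fold lower in the IP on its brightest probe, and 1 of its 3 probes lay above 0. AcCYFIP, named for a partner of the fragile X protein, read -0.37 on its brightest probe and above 0 on both others. Among the adhesion molecules, cad1 and cad2 lay below 0 on all tested probes, at -0.14 and -0.34 on the brightest, though cad1 read 0.02 after normexp with median centring. Fasciclin read 0.03, and -0.32 under that setting, and cad3 read 0.46 on a single tested probe whose control was not well above background.

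Staufen, an RNA-binding protein of transport granules, was 1.48-fold higher in the IP on the AAA array, with all 3 probes above 0. The beta-amyloid precursor protein was 1.71-fold lower on its brightest probe, and PKA (N4), named for a cyclic AMP-dependent kinase, was 2.04-fold lower. Each of these last genes had 1 dimmer probe above 0. Serine dehydratase had the highest brightest-probe ratio of the named genes at 3.34-fold, but its other probe read -0.25. The peptide-processing enzymes PC2 and FUR read -0.29 and -0.05. RNAs of transmitter synthesis lay near 0 on their brightest probes, with choline acetyltransferase at 0.09, dopamine beta-hydroxylase at 0.15 and histidine decarboxylase at 0.10. Other probes of choline acetyltransferase read 0.55 and -0.07, and those of histidine decarboxylase read 0.37 and -0.68. Markers of other cells were also present: the muscle gene Twitchin-like read 0.43 and the blood pigment Hemocyanin read 0.63 with probes on both sides of 0. In all, 20 of the 44 named genes measured on AAA had every tested probe and spot on 1 side and a brightest probe well above background in both channels, 11 above 0 and 9 below, and 2 of the 20 (Panx-1 and NOS) reached 2-fold.

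**Figure D1:**
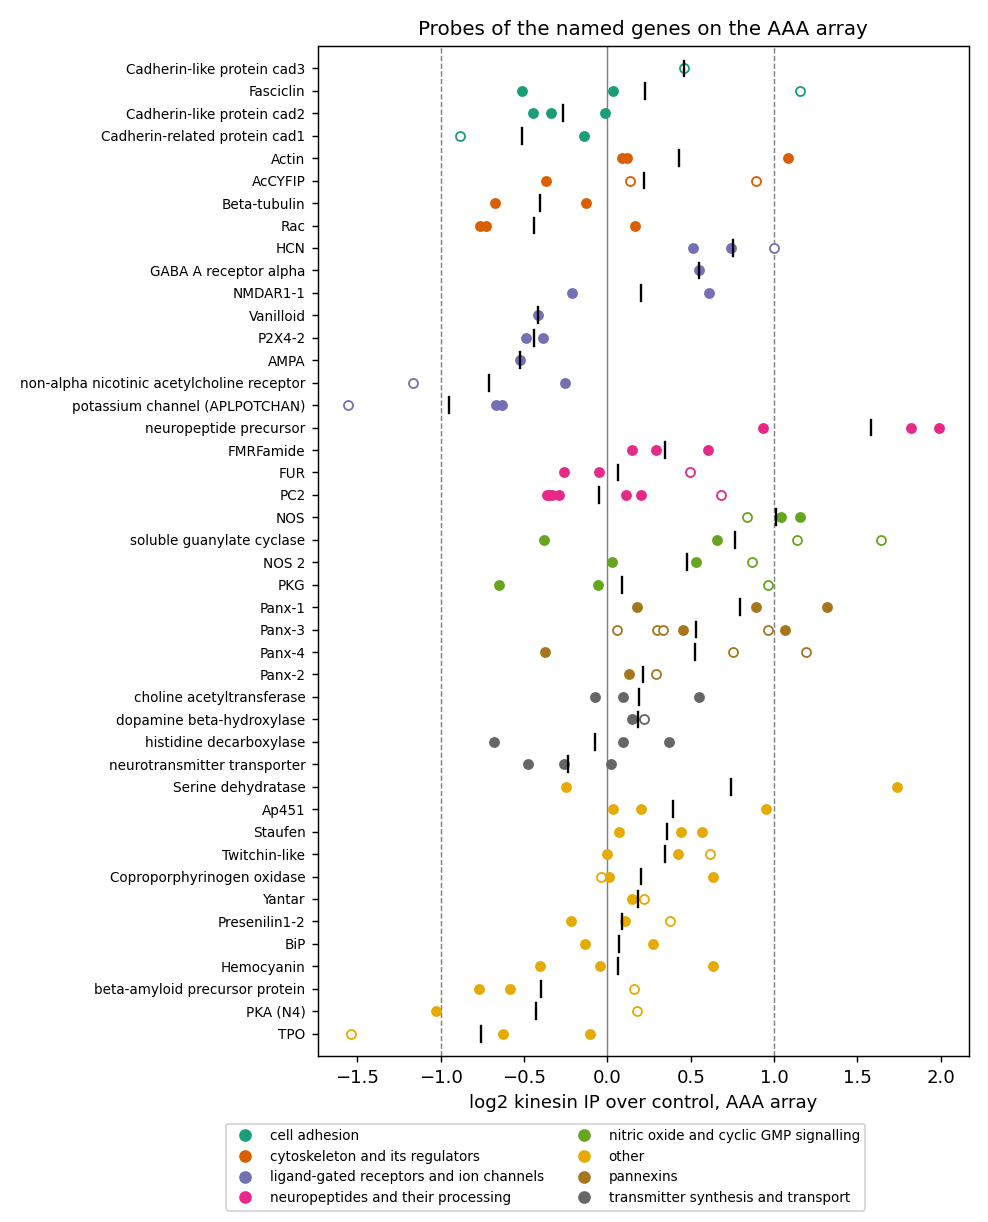
Log2 ratio of kinesin IP over control (horizontal axis) for each tested probe of the named genes on the AAA array, coloured by hand-made group. Filled points were well above background in both channels and open points in 1 channel, short black bars are the mean over probes and dashed lines mark 2-fold. The neuropeptide precursor has the highest mean (1.58), and probes of a gene often lie on both sides of 0.

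The text patterns of the gene lists fixed in advance matched few target names. Of 25 lists, 16 matched none on either array, although genes such as HCN, the potassium channel, PKG, PKA (N4) and BiP belong by function to lists whose patterns missed their abbreviated target names. The other 9 matched at least 1 gene, and no list held more than 4 measured members, so none was placed among random lists. On AAA, the median was 0.97 for the 2 neuropeptides, 0.36 for RNA-binding proteins (Staufen), 0.43 for actin, 0.35 for muscle markers (Twitchin-like) and 0.06 for blood markers (Hemocyanin). It was -0.71 for transmitter receptors, where the pattern matched the nicotinic receptor alone and missed GABA A receptor alpha (0.55), NMDAR1-1 (mean 0.20) and AMPA (-0.53). It was -0.40 for tubulins, -0.44 for small GTPases (Rac) and -0.02 for the 4 adhesion molecules, which was 0.02 without centring. On DAA, 5 lists had a measured member. No control was well above background for 3 of them, whose medians are given with each probe at its bound, or at its computed value where that was below 0. They were 1.80 for the neuropeptides, 1.61 for RNA-binding proteins and 1.35 for small GTPases. The medians of the others were 0.11 for blood markers (-0.18 after normexp with median centring) and -0.52 for adhesion molecules.

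Across the whole AAA array, 1075 of 15921 tested probes (6.75%) were at least 2-fold higher in the IP and 705 (4.43%) at least 2-fold lower. Of the 12766 probes measured in both channels, 558 were higher and 418 lower, or 669 and 332 once these probes were centred on their own median. Of those measured in 1 channel, 337 were at least 2-fold higher and 278 at least 2-fold lower by their bound. The remaining 180 of the higher and 9 of the lower probes passed 2-fold by the computed ratio alone, with a bound under 2-fold. Ratios of different probes of a target agreed less well than ratios of spots of a probe. Across 10985 probes the ratio of a spot correlated with that of the next spot at r = 0.79, whereas across 3701 targets with a second probe the r between probes was 0.20. Among the brighter targets measured in both channels this r was 0.56 over 339 targets. Of the 500 targets with at least 1 of the 2 probes 2-fold higher, 52 had both, and of the 330 with at least 1 probe 2-fold lower, 15 had both. Genes are not independent replicates in these correlations.

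The counts on AAA depended on the background and dye correction. Higher probes made up 60.4% of the probes past 2-fold, against 75.8% of 215 after normexp and loess and 41.4% of 251 after normexp with median centring. The EST clone probe UF_Ac_107232_m1, for a minus-strand target, had the highest ratio measured in both channels with repeated spots, at 6.81-fold (SD 0.34 on the log2 scale, 3 spots). Its sequence was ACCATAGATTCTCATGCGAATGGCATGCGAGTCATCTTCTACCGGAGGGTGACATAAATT. The contig 7.UF_CU.4720.C2 followed at 6.30-fold (SD 0.09, 2 spots), with the probe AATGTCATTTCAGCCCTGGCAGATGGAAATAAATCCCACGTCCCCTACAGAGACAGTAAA. The files pair this contig with no gene, and a kinesin gene was not excluded as its source. The lowest were the clone probes UF_Ac_116398_a1 and UF_Ac_120590_a1. The first, for a minus-strand target, was 4.40-fold lower but with an SD of 2.03 between its 2 spots. The second was 4.08-fold lower (SD 0.47, 2 spots).

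**Figure D2:**
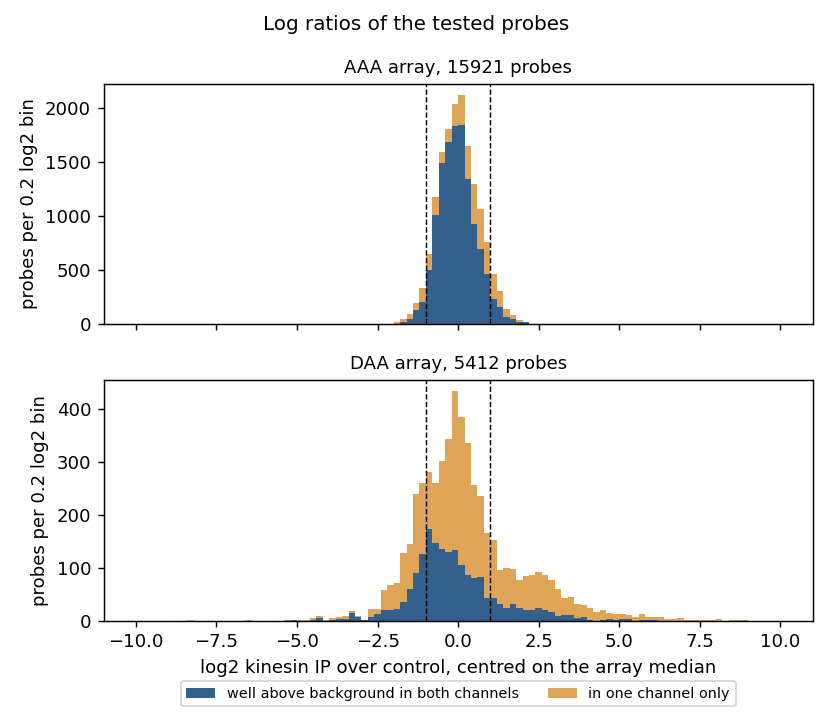
Number of tested probes per 0.2 log2 bin (vertical axes) against the log2 ratio of kinesin IP over control (horizontal axis) on the AAA array (top) and the DAA array (bottom). Blue probes were well above background in both channels, orange probes in 1 channel, and dashed lines mark 2-fold; 6.75% of AAA probes and 24.6% of DAA probes lie beyond it on the IP side.

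On the DAA array, 16 of the 46 named genes were measured, and the peptide precursors again lay on the IP side. FMRFamide was at least 21.0-fold higher in the IP on its brightest probe, and at least 2.38-fold higher on another. The remaining FMRFamide probe read 0.17 with an SD of 0.73 between its 3 spots, which lay on both sides of 0. The neuropeptide precursor was at least 10.9-fold higher on its brightest probe and at least 3.37-fold higher on another (SD 1.85 on the log2 scale, 3 spots), while the remaining probe read -0.21. Staufen was at least 3.05-fold higher on its single measured probe. Rac was at least 4.26-fold higher on its brightest probe. In each of these the control was not well above background. Ap451 was 4.005-fold lower on its brightest probe and lower on both probes measured, each well above background in both channels. With the median non-control spot as background their log2 ratios were -1.02 on the brightest and -0.84 on the other. On AAA the same probes read 0.04 and 0.20, and -0.12 and 0.12 with that background. The remaining Ap451 probe read 0.95 on AAA, so the lower ratio on DAA was not seen on AAA. PKG was at least 3.05-fold lower on DAA with the IP not well above background. HCN read -0.40 and Fasciclin -0.39, which became 0.03 and 0.04 without centring. Hemocyanin read 0.11 and PC2 0.14, which became -0.18 and -0.19 after normexp with median centring. Panx-1 read -0.79 with an SD of 1.15 between its 3 spots, and 0.12 after normexp and loess, with the control not well above background, so its side of 0 is open. With normexp and median centring FMRFamide read 3.53, Staufen 2.60 and Rac 0.88 on their brightest probes, and the neuropeptide precursor read 0.58, below the log2 bound of 3.45 that the scanner software's background gave.

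Over the DAA array, 1330 of 5412 tested probes (24.6%) were at least 2-fold higher in the IP and 1086 (20.1%) at least 2-fold lower. Tested probes were 13.04% of those on the array, and centring took 0.43 off every log2 ratio. Of the 1865 probes measured in both channels, 314 were higher and 435 lower, but 415 were higher and 236 lower once these probes were centred on their own median, so which side held more depended on the centring. By their bound 1006 more were at least 2-fold higher and 651 at least 2-fold lower, and 10 of the higher passed by the computed ratio alone. Higher probes were 55.05% of those past 2-fold, against 81.1% after normexp and loess, 92.7% after normexp with median centring and 76.0% without centring. The contig 7.UF_CU.3.C3746 had the highest ratio measured in both channels, at 73.0-fold on its single spot, with the probe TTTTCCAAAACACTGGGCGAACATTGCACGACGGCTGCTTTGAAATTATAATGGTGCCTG. The contig 7.UF_CU.3.CB339_MINUS followed at 59.0-fold. The processed control signals behind these folds were 130 and 127, beside a median of 230 for probes well above background in that channel. Both folds therefore depend on the background the scanner software took off. The lowest were 7.UF_CU.3.C970_MINUS, 33.3-fold lower, and 7.UF_CU.3.C2847_MINUS, 23.0-fold lower, each on a single spot.

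The arrays shared 795 probes, of which 167 were tested on both. The neuropeptide precursor, FMRFamide and Staufen were higher in the IP on both arrays on their brightest probes. PKG, AMPA and histidine decarboxylase were lower on both on the probe measured on both. On DAA the IP was not well above background for any of them. Their log2 ratios on AAA were -0.65, -0.53 and -0.68, and -0.13, -0.02 and -0.04 with the median non-control spot as background. The brightest AAA probes of PKG and histidine decarboxylase were different ones and read -0.06 and 0.10. For the same probe, Rac read -0.73 on AAA and was at least 4.26-fold higher on DAA, where the control was not well above background. Ap451 was above 0 on AAA and below 0 on DAA on each probe measured on both. Over the 167 probes, 32 were at least 2-fold higher on both arrays, where independent lists of 41 and 90 would share 22.1, and 31 of the 32 had a control below the detection limit on DAA. No probe was at least 2-fold lower on both, and 15 on DAA and 3 on AAA were lower on their own array. Independent lists this short would rarely share a probe, so no conclusion is drawn from the empty overlap. The sign was the same for 138 probes (82.6%, Wilson 95% interval 76.2 to 87.6, counting error only), where the shares above 0 on each array would give 59.8%. Across probes, which are not independent replicates, Pearson's r was 0.53 and Spearman's rho 0.55. Across the 167 probes the IP signals of the arrays correlated at a rho of 0.69 but the control signals at -0.25. On DAA 112 of these probes had a control not well above background. Among the 37 probes measured in both channels of both arrays r was 0.31. Once each array was centred on its probes measured in both channels, 2 of the 37 were at least 2-fold higher on both. The sign was then the same for 64.9% (Wilson 95% interval 48.8 to 78.2), where the shares above 0 would give 51.3%. By limma over the 2 arrays, 0 of the 167 probes passed an adjusted p of 0.05, 7 had an unadjusted p below 0.05, and the smallest adjusted p was 0.36. All 7 were higher in the IP on both arrays, but none had a control well above background on DAA. As a share of the 167, they are fewer than the 0.05 that such a threshold passes where no probe differs.

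**Figure D3:**
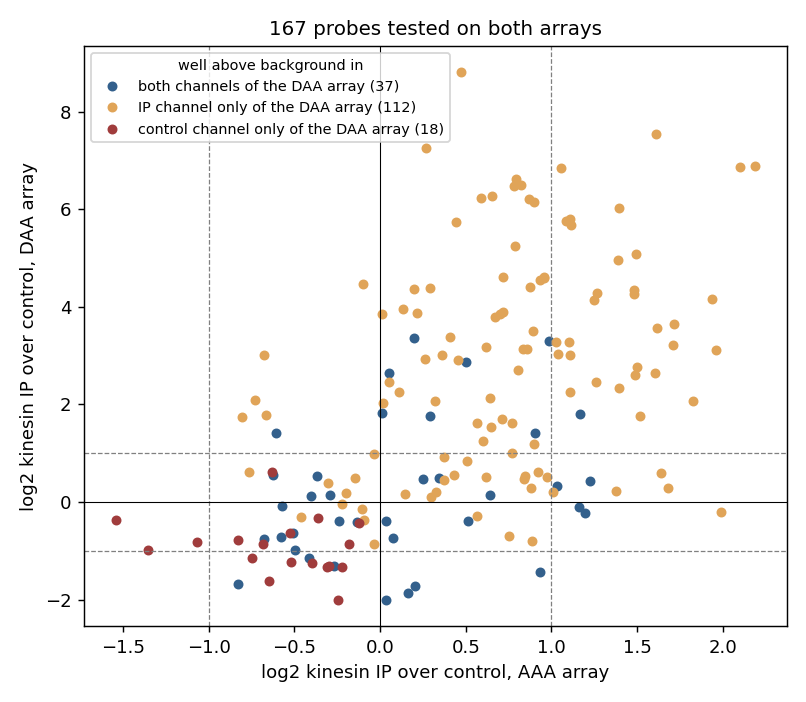
Log2 ratio of kinesin IP over control on the AAA array (horizontal axis) against the DAA array (vertical axis) for the 167 probes tested on both, coloured by the DAA channels well above background. Dashed lines mark 2-fold. The points in the upper right are mostly probes whose control was not well above background on DAA. The lower left beyond 2-fold on both axes is empty, with 3 probes on AAA and 15 on DAA at least 2-fold lower.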

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

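The tests of the background, labelling and GC explanations in this part were chosen after the results were seen. Panx-1, Rac and the potassium channel had computed ratios of opposite sign on the arrays, each past the pooled spot spread of its array, on the same probe. The control was not well above background on DAA for any of the 3, so the DAA ratios are not exact. By the bound Rac was at least 4.26-fold and the potassium channel at least 1.93-fold higher on DAA, while Panx-1 allows no bound. The difference as computed, DAA minus AAA on the log2 scale, was -1.68 for Panx-1 (0.89 on AAA and -0.79 on DAA), 2.82 for Rac (-0.73 and 2.09) and 2.45 for the potassium channel (-0.67 and 1.78). None of these differences was tested, since each array was run once. The 3 DAA spots of the Panx-1 probe had an SD of 1.15. After normexp and loess the DAA value was 0.12 for Panx-1 and -0.17 for the potassium channel, each on the same side of 0 as on AAA. Their signs were also the same on both arrays after normexp with median centring and with the median non-control spot as background, where the potassium channel differed by 0.30 and 0.38. In the series matrix values the signs were opposite, with -0.23 for Panx-1 and 1.79 for the potassium channel on DAA. Their sides of 0 on DAA are therefore open. Rac kept opposite signs under these settings and the series matrix values, with a smallest difference of 1.74. Of 26 named probes tested on both arrays, 14 had opposite signs, and these 3 were the ones past the spot spread on both.

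Control spots that no comparison used also stood out. On the DAA array, negative control spots had a median mean signal of 467 in the control channel, above the 317 of the non-control spots and the 43 of the local background. On AAA the same spots read 74.4, beside 81.0 for non-control spots. On DAA, 92.1% of the non-control spots lay below the negative control median in the control channel, and their median signal after the scanner software's background subtraction was -139. Bright corner spots, another control of the array, read 343 in the DAA control channel and 14261 on AAA.

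Shared probes well above background in the IP channel of both arrays had larger ratios on DAA than on AAA. The median difference over these 148 probes was 1.23. Choosing probes by IP signal can itself favour high ratios on DAA, which was not tested. Over all 795 shared probes with no detection filter the median difference was 0.13, though most DAA spots then hold surrogate values. If too much background had been taken off the DAA control channel, local background should remove most of the difference of 1.23. With local background and normexp, 83.3% of the difference remained after median centring (bootstrap 95% interval 52.9 to 114), and 40.8% after loess (25.9 to 56.4). With the median non-control spot as background it was 119%, though that setting overstated ratios in simulated data where most spots carry signal, as on AAA. No setting removed as much as was set for excess background, but the loess value also missed the bound set against it. The settings differ in dye normalization too, so excess background may account for part of the difference. A control that was weaker by a single factor was the other explanation set, but its test could not decide on it. The interquartile range of the difference over the 37 probes measured in every channel was 1.55 times that of spot noise, under the bound of 2 set for it, but these 37 probes had a median difference of -0.14 (bootstrap 95% interval -0.70 to 0.50) rather than 1.23. Requiring control signal on DAA favours low ratios among these 37 probes. Centring each array on its own median removes a common factor, and an interquartile range does not register one, so no conclusion is drawn on the single factor. A real difference between the pull-downs was not tested and stays open.

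On AAA the ratio was higher for probes richer in G and C, with a Spearman's rho of 0.20 across probes. Probes with 28 to 46 such bases of 60 had a median of 0.15 and 1.27% lower by 2-fold, against -0.16 and 9.18% for those with 11 to 24. If base content set the ratio through dye or hybridisation, the richer of a pair of probes of the same target should be higher in over 60% of pairs. It was higher in 59.3% of 3032 pairs (Wilson 95% interval 57.5 to 61.0), which lies between the bounds set for and against, so a technical share of this trend is possible and its size is open. Removing a linear trend left 1063 probes higher, 929 of them among the original 1075, and 604 lower. No biological explanation was tested.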

How the results depend on the processing

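The background at the median non-control spot, the GC correction and the hand-made groups were added after the data were seen. The cause of each difference was not tested, except that fewer or more probes enter under other filters and thresholds. Against 1075 higher and 705 lower on AAA, the counts were 163 and 52 after normexp and loess, 104 and 147 after normexp with median centring, 170 and 175 with the median non-control spot as background, 669 and 332 for probes measured in both channels and centred on themselves, 2433 and 1570 for single spots, 3002 and 2647 at 1.5-fold, and 41 and 11 at 4-fold. Of the 163 and 104 higher probes under normexp, all were among the 1075. Of the lower probes, all 52 after normexp and loess were among the 705, but 79 of the 147 after normexp with median centring. On DAA, 652 of 653 higher probes after normexp and loess were higher in the main setting too, but 704 of 1072 after normexp with median centring. Against 1330 higher and 1086 lower on DAA, they were 653 and 152 after normexp and loess, 415 and 236 in both channels and centred on themselves (314 and 435 with the centre of all tested probes), 807 and 242 at 4-fold, and 5126 and 93 with no detection filter. On DAA the lower probes alone moved past 1.5 times to 85 after normexp with median centring, 123 with the median non-control spot as background, 558 without centring and 1645 at 1.5-fold. Series matrix values, saturated spots left out and the GC correction kept every count within 1.5 times.

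The number of gene lists above 0 on DAA went from 4 to 9 with no detection filter and to 1 in both channels, and on AAA it stayed within 1.5 times of 5. Shared probes at least 2-fold higher on both arrays went from 32 to 18 after normexp with median centring, 10 by target name and 2 in both channels. Under the main settings, leaving out either array in turn gave 41 to 90 higher and 3 to 15 lower, against 0 lower on both. Their same-sign share went from 82.6% to 52.5% with no filter and 64.9% in both channels. The limma test gave 0 calls under every setting tried. Of 220 values of named genes on AAA under 5 alternatives, 171 moved by less than the spot spread and 21 took the other sign. On DAA this was 55 and 17 of 80. No named gene past 2-fold on its brightest probe took the other sign under these 5. No centring shifts every ratio by 0.04 on AAA and 0.43 on DAA, less than that spread, and the series matrix repeats the scanner software's ratios. Both kept all 44 genes on AAA and all 16 on DAA within it. Under the others (normexp with loess, normexp with median centring, median non-control spot), 29, 24 and 30 of 44 stayed within it on AAA. On DAA 8, 7 and 8 of 16 did. The 21 sign changes on AAA all came from these. Single spots were not run for the shared probes, since spots cannot be paired between arrays, and gene lists without a member measured in both channels gave no value under that filter. No paired analysis was possible because each design had 1 array. Signal over background limits DAA, where 7.40% of non-control spots were well above it in the control channel.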

Other observations

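The test of the AXON and AXOP prefixes together was written before its result was seen, and the other values here were looked at afterwards. Many AAA targets are clones whose names begin with a letter prefix. The clones whose names begin with AXOP had a median log2 ratio of 0.30 over 35 targets, at percentile 99.2 among random sets matched on signal, and 5 of the 35 were at least 2-fold higher and 0 lower. AXON clones had 0.01 over 45 targets, at percentile 56.7. The other 5 prefixes with at least 20 targets (CNS, CNSN, MCC, MCCN and PEG) lay between percentiles 27.7 and 54.1. AXOP is thus the one prefix of 7 in the upper tail, and what the prefixes stand for is not given in the sources used here.

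A hypothesis set beforehand was that clones with the AXON and AXOP prefixes together may be held by the kinesin complex more than other clones, which needed a median above the 95% range of the random sets. That range was -0.16 to 0.14, and the 80 clones had a median of 0.10, at percentile 92.3, so the joint hypothesis was not borne out.

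The AAA array carries probes for both strands of 2436 targets, and both strands were often measured. In the IP channel 1908 targets were well above background on both strands, 286 on the plus strand alone and 190 on the minus strand alone. Across the 1996 targets with both strands tested, the log ratios of the strands showed almost no relation (Pearson's r = 0.02, Spearman's rho = 0.01), and 4 had both strands at least 2-fold higher in the IP, against 189 with at least 1.

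Among the targets on both arrays with at least 2 tested probes, 5 of 49 had every probe at least 2-fold higher on both. The contig 7.UF_CU.sd.94.C1 had this on 3 probes and the contig 7.UF_CU.sd.42.CB1_MINUS on 2. Their log2 ratios on AAA ran from 1.39 to 1.61 and from 1.11 to 1.72. On DAA no control was well above background, and the lowest of their log2 ratios was at least 2.65 and at least 3.01 by the bound. All 5 targets stayed at least 2-fold higher on both arrays with each dim channel at its bound, after normexp and loess, and in the series matrix values. After normexp with median centring, and with the median non-control spot as background, this held for 3 of the 5, and 7.UF_CU.sd.42.CB1_MINUS lost it with a lowest AAA ratio of 0.72 and 0.76.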
